A study of Homo sapiens with 12 samples.

How the data were processed

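Gene expression had been measured by the authors on Affymetrix arrays in 12 samples of 4 groups: the human prostate cancer lines DU145 and 22Rv1, and the docetaxel-resistant lines DU145-DR and 22Rv1-DR. Replicates 1 and 2 of each group were on an array type with 22215 probe sets (8 arrays), and replicate 3 of each group was on a larger array type with 54613 probe sets (4 arrays), which includes the 22215. The deposited values are probe-set intensity on a linear scale, from 7.52 to 31216 in the 8-array table and from 6.73 to 30786 in the 4-array table. The log2 of 100% of them is a number of 2 decimals, within 1e-05. MAS5 and RMA are named in the submitters' processing notes, and their roles, order and versions are not given in the sources used here, nor are background correction, scaling and the annotation. In the 8-array table the parental and the resistant array of the same line and replicate number had nearly the same distribution, while the DU145 arrays had a higher floor (5th percentile 35.8 to 38.6) than the 22Rv1 arrays (11.5 to 12.3). Levels are therefore not comparable between the lines in that table, nor between the tables, and a change from or to a value near the floor is a bound that depends on it. Whether replicates are separate cultures is not given in the sources used here.

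The number of arrays limits the precision. Probe sets were named from the annotation supplied for each array type. Those with 1 gene symbol (19064 and 41091) were used, those with several (1043 and 1801) or none (2108 and 11721) were left out, and so were 31 and 59 probe sets of Y-linked or X-inactivation genes. Each of the 11939 and 19740 genes was represented by the probe set with the highest mean log2 value among those not prone to cross-hybridization by their name. Where every probe set of a gene was named as prone, the highest of these was used. This held for IFITM2, IFITM3, HLA-B, HLA-C, KRT8, KRT18 and TUBB3, whose readings may therefore not be specific. Genes whose mean exceeded the 40th percentile of all values (log2 6.49, intensity 74.0) in no group were left out as dim, which left 9713 genes.

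Values were taken as log2 of the intensity plus 16. All 8 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, 4 residual and 4.47 prior degrees of freedom), with a term for each of the 4 groups and no block. Contrasts were DU145-DR against DU145, 22Rv1-DR against 22Rv1, their difference (22Rv1 change minus DU145 change) and 22Rv1 against DU145. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, from limma's two-sided moderated test. The third pair gave resistant minus parental differences in the 4-array table with no test. The share of genes with the same sign there has a 95% exact binomial interval, which treats genes as independent and is descriptive.

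A total of 37 gene lists with 1009 genes, of which 752 were tested, covered drug transport, tubulins, epithelial and mesenchymal states, antigen presentation, signalling, stress, cell cycle, metabolism, other cell types and line identity. The lists, comparisons, test and rule for named genes were set before the data were examined, but with the subjects of the publication known. Lists with at least 5 tested genes (36 of 37) were tested with camera at a preset correlation of 0.01 and adjusted over the lists; camera with an estimated correlation and fry were alternatives. With an estimated correlation none of the list calls held, 0 in each of the 3 comparisons.

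Genes are named by a rule: the 10 largest rises and falls in each line among those that passed, did not overlap between groups and had the same sign on the third pair; up to 4 members of each list past the threshold; the 10 largest differences between lines; the 10 genes changed the same way in both lines with the largest smaller change; a set of 30 genes of drug transport, epithelium, class I, Notch, Hedgehog and apoptosis whatever their result, some of which are not reported here; and, on the larger array type only, the 5 largest differences each way.

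The replicate numbers were checked for pairing. In the 8-array table the deviations of replicate 1 from its group's mean correlated across genes between parental and resistant arrays at 0.693 for DU145 and 0.792 for 22Rv1, against 0.0688 to 0.123 across lines. Over 12 arrays the values by pair were 0.703, 0.532 and 0.539 for DU145 and 0.607, 0.603 and 0.469 for 22Rv1. The 12-array values include the offset between the array types, which arrays of 1 table share, so they cannot test pairing. The 8-array values pair replicates 1 and 2 within a line. A fit with a block for each line and replicate number (2 residual and 3.32 prior degrees of freedom) was therefore an alternative.

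Other alternatives were quantile normalization, a shift of the arrays to 1 median, pseudocounts of 1 and 64, no filter on dim genes and one at the 60th percentile, the mean of a gene's probe sets, only the 4 arrays compared, an intensity trend with a robust prior, all 12 arrays in 1 fit with the table or the replicate as a block, an adjusted p under 0.01, a log2 change of at least 1, and leaving out each array, where the lone array of a group is assumed to vary like the other groups. Added after the data were seen were a filter percentile within each array, quantile normalization within each line, the estimated correlation with the block, and the same sign in each replicate pair.

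The 10 tested genes nearest to ABCB1 on its chromosome were compared with those around each other gene, and windows of 21 neighbouring genes with 1000 shuffles of gene order. The procedure was tested on simulated data with 9713 genes. Of 100 genes changed by 1 on the log2 scale it recovered 11 in DU145 and 3 in 22Rv1, and of 100 changed by 2 it recovered 87 and 76, with 0 false calls; with the block it recovered 66 and 75, and 90 and 92, with 2 and 0 false calls. The simulated arrays took their replicate offsets and their spread from the fit with the block. The gain from the block was therefore built in and cannot show which fit suits the real arrays. A list shifted by 0.5 was recovered in both lines, with 1 and 0 other lists called. The simulated noise was independent between genes, whereas the estimated correlation was 0.85 for the mitosis and 0.42 for the S phase list. The simulation therefore cannot show how often list calls are false where members correlate. Of the windows in a run of 60 shifted genes, 60 and 58 were past the limit, with 15 and 6 others past it outside the run and 13 and 3 where no run was shifted, and 4 of 100 random lists fell outside their 95% range. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.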

Results

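Docetaxel, a taxane that stabilises microtubules, is given in advanced prostate cancer, and the series asked which genes differ between prostate cancer cells selected for resistance to it and the cells they came from. The parental lines were DU145 and 22Rv1, and the resistant lines derived from them were DU145-DR and 22Rv1-DR. Changes are resistant minus parental on the log2 scale, each with the standard error that limma gave over 2 arrays per group. Replicate 3 of each group, 1 array per group on a larger array type, gave the third pair of values, with no test. Parental cells were grown without docetaxel and resistant cells with it, so each comparison joins resistance with exposure to the drug.

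DU145-DR cells had far more mRNA of ABCB1, the gene of the drug efflux pump P-glycoprotein, than DU145 cells (log2 change 5.15 ± 0.50, adjusted p = 0.000497; 8.64 on the third pair). The ABCB1 intensity was 78.8 and 68.1 on the parental arrays and 6165 and 1618 on the resistant arrays of replicates 1 and 2. The parental values lay near the 25th percentile of their arrays (76.1 and 62.7), so the change is possibly only a lower bound. CDH1, which encodes the adhesion molecule E-cadherin, fell by 5.74 ± 0.23 (adjusted p = 7.74e-06), and KRT19, an epithelial keratin, fell by 3.70 ± 0.31 (adjusted p = 0.000274). SNAI2, a transcription factor that represses E-cadherin, rose by 5.35 ± 0.22 (adjusted p = 7.74e-06). Of 9713 genes tested, 1069 changed, 537 up and 532 down, and 734 of these moved by at least 1 on the log2 scale.

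Among the largest rises in DU145-DR cells, COL4A5, a chain of basement membrane collagen, rose by 6.01 ± 0.29, TKTL1, a transketolase-like protein, by 5.41 ± 0.41, FSTL1, a secreted glycoprotein, by 4.52 ± 0.21, and SDC2, a cell-surface heparan sulfate proteoglycan, by 4.32 ± 0.31. AKR1C3, an aldo-keto reductase of steroid metabolism, rose by 4.05 ± 0.19 but differed by only 0.31 on the third pair. SCG5, RTN1 and SPOCK1 completed the 10 largest rises, with changes of 4.20, 3.89 and 3.86. The largest falls were those of BCHE, the gene of butyrylcholinesterase, which fell by 6.72 ± 0.25, and EREG, a ligand of the epidermal growth factor receptor, which fell by 5.82 ± 0.22. CDH3 (P-cadherin) fell by 4.26 ± 0.22, SPINT2, an inhibitor of serine proteases, fell by 5.04 ± 0.22, and NKX2-1, a transcription factor of lung and thyroid, fell by 4.13 ± 0.20. LMO3, KYNU, CD24 and MTUS1 changed by -4.59, -4.22, -4.21 and -4.06.

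Luminal epithelial genes were shifted down in DU145-DR cells: of 23 tested, 9 fell, 0 rose and 14 did not pass (camera adjusted p = 7.38e-06; adjusted p = 0.0992 with an estimated correlation). Adjusted over the list alone, 10 fell and 1 rose. The list median was -0.61, and on the third pair -1.60. Besides CDH1 and KRT19, CD24 fell by 4.21 ± 0.56, and KRT18, a keratin of simple epithelia, changed by -1.01 ± 0.22. The KRT18 call was lost without DU145 replicate 1 (adjusted p = 0.0531), DU145 replicate 2 (0.110) or DU145-DR replicate 1 (0.0530). KRT8, the partner of KRT18, gave 0.11 ± 0.19 (adjusted p = 0.867). The luminal list was written with the subjects of the publication known, so its direction is not independent evidence.

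Genes of class I antigen presentation were also shifted down: 7 of 18 fell, 0 rose and 11 did not pass (adjusted p = 1.41e-07; adjusted p = 0.324 with an estimated correlation), and 9 fell when adjusted over the list alone. PSMB9 and PSMB8, subunits of the immunoproteasome, fell, at -3.76 ± 0.36 and -2.20 ± 0.23. TAP1, which carries peptides into the endoplasmic reticulum, fell by 1.62 ± 0.18, and PSME1, a proteasome activator, fell by 2.08 ± 0.30. The heavy chains HLA-B and HLA-C gave -0.46 ± 0.28 and -0.55 ± 0.21, and B2M, the light chain, gave -0.32 ± 0.21; none of these 3 passed (adjusted p = 0.383, 0.146 and 0.437). With the replicate number as a block, all 3 passed (adjusted p = 0.0203, 0.0154 and 0.0361). The class I list, too, was written with the publication's subjects known and is not independent evidence. Of 11 class II genes, 2 fell and 9 did not pass (adjusted p = 0.0312; adjusted p = 0.324 with an estimated correlation), 4 fell when adjusted over the list alone, and HLA-DRA fell by 1.39 ± 0.20. The class II call was lost without DU145 replicate 1 (adjusted p = 0.0793) or DU145-DR replicate 2 (0.377), and after quantile normalization (0.0831).

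Interferon-induced genes were shifted down in DU145-DR cells: 16 of 34 fell, 0 rose and 18 did not pass (adjusted p = 2.99e-08; adjusted p = 0.165 with an estimated correlation). Adjusted over the list alone, 19 fell and 1 rose. IFITM3 and IFITM2, membrane proteins that restrict virus entry, fell, at -3.68 ± 0.25 and -2.94 ± 0.26, and GBP1, an interferon-induced GTPase, fell by 2.27 ± 0.45. The list median was -0.80, and -1.36 on the third pair.

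Mesenchymal genes were shifted up in DU145-DR cells, with 9 of 38 higher, 1 lower and 28 not past the threshold (adjusted p = 0.000649; adjusted p = 0.165 with an estimated correlation). Adjusted over the list alone, 13 rose and 2 fell. IGFBP3, which binds insulin-like growth factors, rose by 3.37 ± 0.21, and LOX, which cross-links collagen, by 2.74 ± 0.21. Of 11 fibroblast markers, 2 rose and 0 fell in the same cells (list adjusted p = 0.268): FBN1, a microfibril glycoprotein, by 2.02 ± 0.30 (2.22 on the third pair), and FBLN1, whose call was lost without any 1 of 7 arrays, all except DU145-DR replicate 1 (adjusted p from 0.0724 to 0.179). VIM, the mesenchymal intermediate filament gene, gave 0.64 ± 0.21 (adjusted p = 0.0947). The list median was 0.19 on the tested arrays and -0.12 on the third pair, the opposite sign, although SNAI2, FSTL1, IGFBP3 and LOX were higher there by 2.81, 2.86, 3.73 and 2.11. With both tables in 1 fit and the table as a block, the list no longer passed (adjusted p = 0.0602).

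Immediate early genes, which growth and stress signals switch on within minutes, were shifted up in DU145-DR cells: 12 of 23 rose, 0 fell and 11 did not pass (adjusted p = 3.79e-09; adjusted p = 0.0992 with an estimated correlation), and 15 rose when adjusted over the list alone. DUSP4 and DUSP1, phosphatases that switch off MAP kinases, rose by 2.22 ± 0.20 and 1.96 ± 0.18, and the stress transcription factor ATF3 by 2.09 ± 0.20. EGR1 rose by 1.67 ± 0.22, but gave -1.75 on the third pair, where the list median was 0.39 against 1.05 on the tested arrays.

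Of 28 hypoxia and glycolysis genes, 7 rose and 21 did not pass (adjusted p = 0.0328; adjusted p = 0.817 with an estimated correlation), among them ANGPTL4 by 2.56 ± 0.28 and ADM, a vasodilator peptide, by 2.51 ± 0.19. Of 24 targets of the oxidative stress factor NRF2, 6 rose, 1 fell and 17 did not pass (adjusted p = 0.0298; adjusted p = 0.763 with an estimated correlation), and the cystine transporter SLC7A11 rose by 1.36 ± 0.19. Of 16 heat shock genes, 4 rose and 12 did not pass (adjusted p = 0.0198; adjusted p = 0.763 with an estimated correlation), with HSPB8, a small heat shock protein, up by 2.82 ± 0.28. Of 30 apoptosis regulators, 5 fell, 1 rose and 24 did not pass (adjusted p = 0.0388; adjusted p = 0.697 with an estimated correlation), and BCL2L1, an inhibitor of apoptosis, fell by 1.54 ± 0.25. BCL2 and MCL1 gave 0.03 ± 0.27 and 0.55 ± 0.21 and did not pass (adjusted p = 0.990 and 0.150). Of 49 mitosis genes, 3 fell and 46 did not pass (adjusted p = 0.0205; adjusted p = 0.892 with an estimated correlation); the median was -0.29, and 0.12 on the third pair. The 3 were BUB1, MKI67 and TOP2A, whose calls were lost without DU145 replicate 1 (adjusted p = 0.114, 0.106 and 0.0598) or DU145 replicate 2 (0.125, 0.151 and 0.111), and that of MKI67 also without DU145-DR replicate 1 (0.0540) or either 22Rv1-DR replicate (0.0525). Adjusted over the list alone, 7 hypoxia genes rose and 1 fell, 6 NRF2 targets rose and 1 fell, 4 heat shock genes rose, 6 apoptosis regulators fell and 1 rose, and 3 mitosis genes fell. Each of these 5 list calls was lost without at least 1 array. The hypoxia call was lost without DU145 replicate 1 (adjusted p = 0.162) or DU145-DR replicate 1 (0.254), and the NRF2 call without DU145 replicate 1 (0.0793) or DU145-DR replicate 2 (0.170). The heat shock call was lost without DU145 replicate 1 (0.0793) or DU145-DR replicate 2 (0.128), and the BCL2 call without DU145 replicate 1 (0.0629), DU145 replicate 2 (0.0776) or DU145-DR replicate 2 (0.286). The mitosis call was lost without DU145 replicate 2 (0.206), and its direction turned without DU145-DR replicate 1 (0.475). With the replicate number as a block, the hypoxia, NRF2 and BCL2 calls were lost (adjusted p = 0.0584 for each). After quantile normalization the hypoxia and BCL2 calls were lost (0.0718 and 0.0754). All 12 arrays in 1 fit with the table as a block lost the NRF2, mitosis, BCL2 and hypoxia calls (camera adjusted p = 0.346, 0.285, 0.0794 and 0.0689). A stricter filter on dim genes lost the NRF2 and hypoxia calls (0.0631 for each).

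Notch and Hedgehog signalling, both subjects of the publication when these lists were written, were not shifted as lists in DU145-DR cells by camera; by fry, another list test, Notch was shifted up (adjusted p = 0.0360), with a median of 0.06 on the tested arrays but -0.11, the opposite sign, on the third pair. Of 23 Notch genes, 5 rose, 0 fell and 18 did not pass (list adjusted p = 0.156), and 5 rose and 2 fell when adjusted over the list alone. HEY1, a transcriptional target of Notch, rose by 2.45 ± 0.26 (adjusted p = 0.000809), the receptor gene NOTCH2 by 1.98 ± 0.23 and the ligand gene JAG1 by 1.53 ± 0.23, with 2.74, 2.21 and 1.17 on the third pair. HES1, another Notch target, rose by 2.13 ± 0.20 but gave -0.37 on the third pair. NOTCH1 and NOTCH3 gave 0.46 ± 0.24 and -0.12 ± 0.45 and did not pass (adjusted p = 0.295 and 0.970). Of 12 Hedgehog genes, 1 rose, also when adjusted over the list alone, and 11 did not pass (list adjusted p = 0.888, with a median of -0.02 and a mean of 0.05). The gene that rose, the transcription factor GLI3, changed by 0.80 ± 0.19 (adjusted p = 0.0322), and its call was lost without any 1 of 7 arrays, all except DU145-DR replicate 2, with adjusted p from 0.0659 to 0.138. SMO, PTCH1 and GLI2 gave -0.18, -0.54 and 0.10 (adjusted p = 0.769, 0.372 and 0.928). GLI1 was too dim to be tested.

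The count of changed genes in DU145-DR cells was 489 without DU145 replicate 1 (179 up, 310 down) and 523 without DU145 replicate 2 (308 up, 215 down). It was 1080 without DU145-DR replicate 1 (631 up, 449 down) and 1523 without DU145-DR replicate 2 (555 up, 968 down), so the balance of directions depended on the arrays kept. List members that stayed past the threshold without each array in turn were 5 of 9 luminal, 5 of 7 class I, 1 of 2 class II, 6 of 16 interferon, 7 of 10 mesenchymal, 5 of 12 immediate early, 3 of 7 hypoxia, 4 of 7 NRF2, 1 of 4 heat shock, 1 of 6 apoptosis, 0 of 3 mitosis and 4 of 5 Notch genes. On the third pair the list medians were -0.93 for class I, -0.40 for class II, 0.18 for hypoxia, 0.55 for heat shock and -0.16 for apoptosis genes, and only 0.01 for NRF2 targets against 0.16 on the tested arrays. By fry the mitosis and heat shock lists did not pass (adjusted p = 0.592 and 0.0869), while the Notch, neuroendocrine and inflammatory lists did (0.0360, 0.0360 and 0.00675), with medians of -0.11, -0.23 and -0.17 on the third pair. Leaving out 1 array of DU145 or DU145-DR also breaks a replicate pair. The arrays of a pair had like distributions (mean quantile differences of 0.0378 and 0.0230 on the log2 scale). DU145 replicates 1 and 2 were further apart (0.214). Counts and calls without 1 array may therefore reflect this imbalance as well as the genes, and these were not separated. All member counts given are from the fit without the block. With it more members passed in 33 of 37 lists and fewer in 0, among them 14 falling and 2 rising mitosis genes and 6 rising and 2 falling Notch genes. With the replicate number as a block the count of changed genes was 3445, and all p-values measure only the spread between these arrays, which is possibly technical, since separate cultures are not stated.

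**Figure D1:**
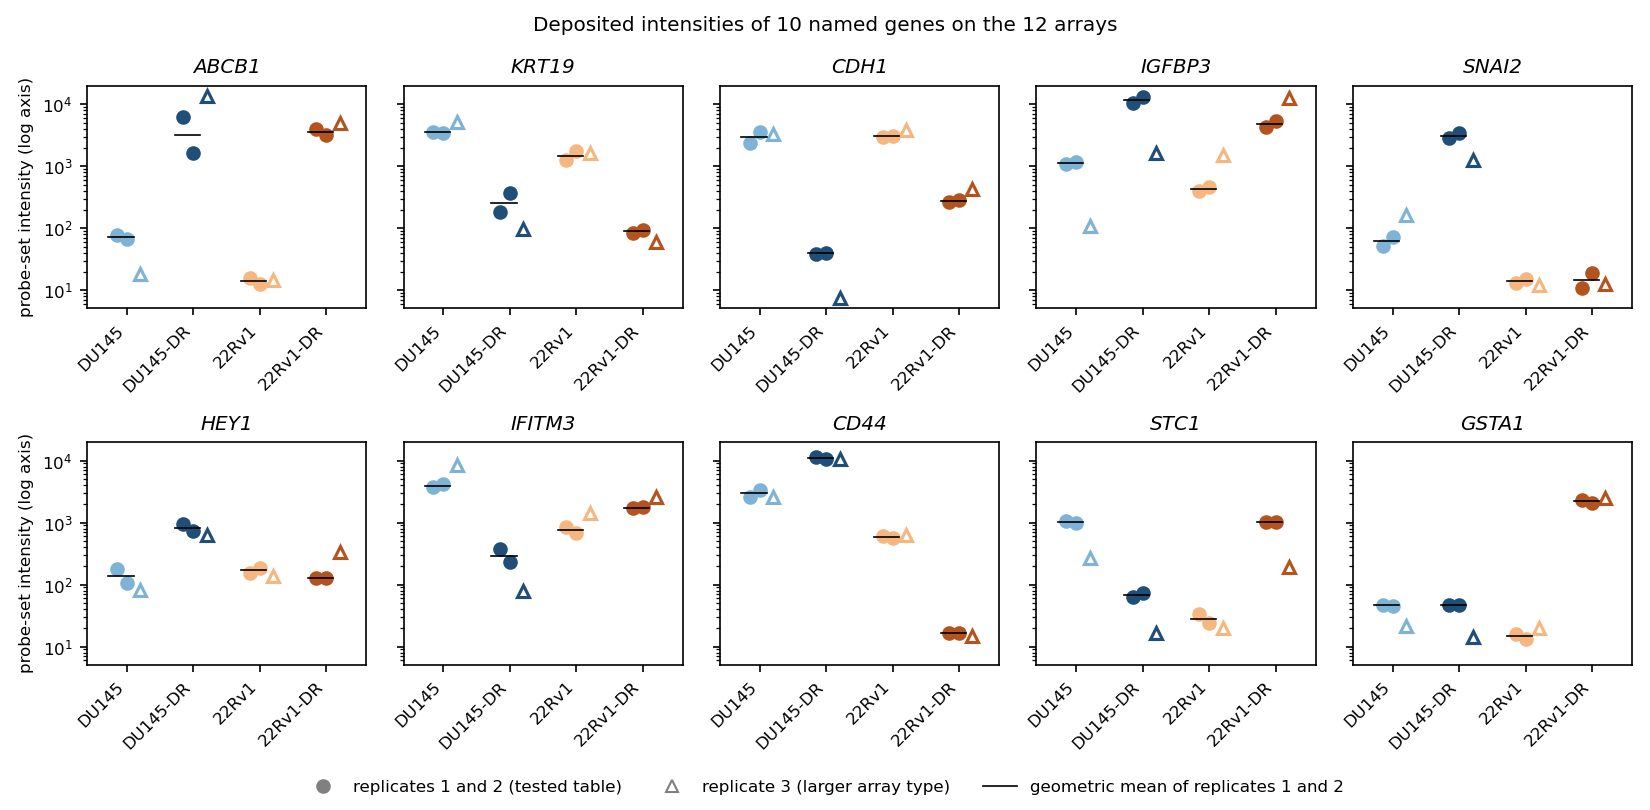
Probe-set intensity (log axis) of 10 genes on all 12 arrays, with replicates 1 and 2 filled, replicate 3 (the larger array type) as open triangles and the geometric mean of replicates 1 and 2 as a line. ABCB1 rose and KRT19 fell in both resistant lines, while CD44 rose in DU145-DR and fell in 22Rv1-DR cells.

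In 22Rv1-DR cells ABCB1 rose by 6.91 ± 0.50 (adjusted p = 0.000156; 7.36 on the third pair), from intensities of 15.6 and 12.8 to 3984 and 3259. The parental values lay just above the 5th percentile of their arrays (12.3 and 11.7), so this change is a lower bound set by the floor and the 16 added to each intensity. CDH1 and KRT19 fell here too, at -3.38 ± 0.23 and -3.83 ± 0.31, and CD44, the hyaluronan receptor gene, fell by 4.22 ± 0.19 (adjusted p = 0.000116, 0.000234 and 1.66e-05). GSTA1, a glutathione S-transferase, rose by 6.17 ± 0.17, and LUM, a collagen-binding proteoglycan, by 6.04 ± 0.23, although LUM was higher by only 1.20 on the third pair. Of 9713 genes tested, 540 changed, 304 up and 236 down, and 448 of these moved by at least 1 on the log2 scale.

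The other large rises in 22Rv1-DR cells were those of MAGEC2, a cancer-testis antigen, by 5.11 ± 0.20, the interleukin 13 receptor gene IL13RA2 by 4.57 ± 0.32, STC1, a secreted glycoprotein hormone, by 4.56 ± 0.19, the nuclear receptor gene NR5A2 by 4.26 ± 0.25, and LYN, a SRC family kinase, by 4.19 ± 0.21. PRPS2 and IMPA1 changed by 3.59 and 3.50. Of the largest falls, CGA, the common subunit of glycoprotein hormones, fell by 4.46 ± 0.25, MAOA, monoamine oxidase A, fell by 4.41 ± 0.23, PMEPA1, an androgen-responsive gene, fell by 4.25 ± 0.53, and DKK1, a Wnt antagonist, fell by 3.98 ± 0.22. HGF, the ligand of the MET receptor, fell by 3.89 ± 0.21 and NMB, the neuropeptide neuromedin B, fell by 3.93 ± 0.36. The HGF probe set tested gave -1.24 on the third pair, where the highest of its 5 probe sets gave 1.62, the opposite sign. PRUNE2, SLC2A10 and CRIP1 changed by -4.36, -4.10 and -4.09, of which CRIP1 gave only -0.43 on the third pair.

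S phase and DNA replication genes were shifted down in 22Rv1-DR cells (median -0.65): 4 of 40 fell, 0 rose and 36 did not pass (adjusted p = 1.74e-14; adjusted p = 0.429 with an estimated correlation), and 18 fell when adjusted over the list alone. The 4 were GINS2, MCM2, LIG1 and E2F1, with -1.20 ± 0.22 for GINS2, -1.17 ± 0.21 for MCM2 and -0.79 ± 0.18 for E2F1, whose other probe set did not share the sign. MCM2 encodes a subunit of the replicative helicase. These calls were lost without any 1 of the 4 arrays of 22Rv1 and 22Rv1-DR, with adjusted p from 0.103 to 0.130 for GINS2, 0.0847 to 0.139 for MCM2, 0.153 to 0.293 for LIG1 and 0.185 to 0.348 for E2F1, and that of LIG1 also without either DU145 array (0.0690). The list median was only -0.08 on the third pair. Mitosis genes had a median of -0.12 and 1 of 49 rose (adjusted p = 0.197); the gene, the mitotic kinase AURKB, at 1.44 ± 0.26, lost its call without any 1 of the same 4 arrays (adjusted p from 0.0841 to 0.113).

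Cholesterol biosynthesis genes were shifted down in 22Rv1-DR cells (median -0.58): 4 of 18 fell, 0 rose and 14 did not pass (adjusted p = 2.71e-09; adjusted p = 0.245 with an estimated correlation), and 7 fell when adjusted over the list alone. SQLE, the enzyme that forms squalene epoxide, fell by 1.59 ± 0.19 and ACAT2 fell by 1.98 ± 0.25. The other 2, HMGCS1 and IDI1, lost their calls without any 1 of the 4 arrays of 22Rv1 and 22Rv1-DR (adjusted p from 0.125 to 0.326 and from 0.0649 to 0.101). The list median on the third pair was 0.06, and ACAT2 gave 0.01 there.

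Progenitor cell markers were shifted down in 22Rv1-DR cells: 5 of 17 fell, 1 rose and 11 did not pass (adjusted p = 0.00535; adjusted p = 0.245 with an estimated correlation), and the counts were 5 and 1 when adjusted over the list alone. CD44 fell, as did the transcription factor KLF4, at -2.56 ± 0.25, and the Wnt-associated receptor LGR5, at -2.15 ± 0.17, while ABCG2, a drug efflux pump also found in stem cells, rose by 1.64 ± 0.22. Drug transporters were shifted up, with 3 of 13 higher, 0 lower and 10 not past the threshold (adjusted p = 0.0222; adjusted p = 0.245 with an estimated correlation); adjusted over the list alone, 4 rose and 1 fell. Besides ABCB1 and ABCG2, ABCC4, a pump of organic anions, rose by 2.07 ± 0.20. The transporter call was lost without 22Rv1-DR replicate 2, with the replicate number as a block (camera adjusted p = 0.122) and after quantile normalization (0.168). It was also lost with a pseudocount of 64 (0.0706) and with no filter on dim genes (0.0877). All 12 arrays in 1 fit with the replicate as a block lost it too (0.118). The progenitor call was lost with a stricter filter on dim genes (0.0683) and with the mean of a gene's probe sets (0.0761). In DU145-DR cells 1 of the 13 transporters rose, 3 fell and 9 did not pass (adjusted p = 0.585, with a median of -0.06 and a mean of 0.15), and SLCO1B3, a hepatic uptake transporter, fell by 2.56 ± 0.25 there. ABCG2 and ABCC4 were the others that fell, at -1.26 ± 0.22 and -1.07 ± 0.20, and lost their calls without DU145 replicate 2 (adjusted p = 0.0562 and 0.0755). ABCC1, the gene of the efflux pump MRP1, gave 0.56 ± 0.31 and 0.75 ± 0.31 in DU145-DR and 22Rv1-DR cells (adjusted p = 0.322 and 0.264), and passed in both with the replicate number as a block (0.00673 and 0.00417).

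Mesenchymal genes were shifted up in 22Rv1-DR cells, with 6 of 38 higher, 2 lower and 30 not past the threshold (adjusted p = 0.00867; adjusted p = 0.245 with an estimated correlation); adjusted over the list alone, 7 rose and 2 fell. LUM, IGFBP3 and COL6A1, a chain of collagen VI, rose, the last of these by 1.94 ± 0.18 with 4 of its 8 probe sets of that sign, and TNC, an extracellular matrix glycoprotein, fell by 2.52 ± 0.26. VIM changed by -1.02 ± 0.21 (adjusted p = 0.0263), a call lost without any 1 of the 4 arrays of 22Rv1 and 22Rv1-DR (adjusted p from 0.0803 to 0.282). LUM and COL6A3 were the fibroblast markers that rose, 2 of 11 (list adjusted p = 0.0801). Among luminal genes 5 of 23 fell, 2 rose and 16 did not pass (adjusted p = 0.0184; adjusted p = 0.245 with an estimated correlation); adjusted over the list alone, 7 fell and 3 rose. SPDEF, a transcription factor of secretory epithelium, fell by 3.18 ± 0.28 with 3 of its 5 probe sets of that sign, and CLDN4, a tight junction protein, fell by 2.52 ± 0.18. Androgen-responsive genes were shifted down, with 3 of 12 lower, 1 higher and 8 not past the threshold (adjusted p = 0.0184; adjusted p = 0.245 with an estimated correlation); adjusted over the list alone, 7 fell and 2 rose. The list median was -0.74 on the tested arrays but only -0.08 on the third pair. PMEPA1 fell and ABCC4 rose, while KLK3, the gene of prostate-specific antigen, gave -0.78 ± 0.39 (adjusted p = 0.398; 0.00724 with the replicate number as a block) and 0.55 on the third pair. The luminal and androgen-responsive lists were written with the publication's subjects known. Both calls were lost with the replicate number as a block (camera adjusted p = 0.117 and 0.0632) and after quantile normalization (0.0565 and 0.0750). All 12 arrays in 1 fit with the table as a block lost both too (0.0532 and 0.121). The androgen-responsive call was also lost with a stricter filter on dim genes (0.129) and with the mean of a gene's probe sets (0.0975). The mesenchymal call was lost with the mean of a gene's probe sets (0.0761). KRT8 and KRT18 gave -0.05 ± 0.19 and -0.45 ± 0.22 (adjusted p = 1.00 and 0.363).

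Of 18 class I genes, 2 fell in 22Rv1-DR cells, 0 rose and 16 did not pass (adjusted p = 0.00867; adjusted p = 0.738 with an estimated correlation), and 3 fell when adjusted over the list alone, again a list written with the publication's subjects known. HLA-C fell by 1.68 ± 0.21 (-3.59 on the third pair), and HLA-B changed by -1.38 ± 0.28 (-2.58 on the third pair), a call lost without any 1 of the 4 arrays of 22Rv1 and 22Rv1-DR (adjusted p from 0.0753 to 0.20). B2M gave 0.07 ± 0.21 (adjusted p = 1.00), but -0.92, the opposite sign, on the third pair. Of 23 Notch and 12 Hedgehog genes, 0 rose and 0 fell in 22Rv1-DR cells by limma, also when adjusted over each list alone (list adjusted p = 0.799 and 0.345). At an unadjusted p under 0.05, 3 Notch genes were higher and 2 Hedgehog genes lower. These zeros hold only without the block: with the replicate number as a block 5 Notch genes rose and 1 fell, and 1 Hedgehog gene rose and 2 fell. NOTCH1, NOTCH2, NOTCH3, JAG1, HES1 and HEY1 gave -0.51, 0.43, -0.17, 0.08, 0.66 and -0.36, and SMO, PTCH1, GLI2 and GLI3 gave -0.01, -1.01, -0.01 and -0.63. BCL2, BCL2L1 and MCL1 gave -0.07, 0.12 and 0.19, and none of these passed in the fit without the block. With it NOTCH2, HES1, PTCH1 and GLI3 passed (adjusted p = 0.0335, 0.0199, 0.00215 and 0.0162). On the third pair NOTCH2, HES1 and GLI3 had the opposite sign, at -0.38, -0.03 and 0.05, while PTCH1 kept its sign at -1.47. HEY1 also had the opposite sign there, at 1.21.

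The count of changed genes in 22Rv1-DR cells was 219 without 22Rv1 replicate 1, 214 without 22Rv1 replicate 2, 219 and 224 without 22Rv1-DR replicates 1 and 2, and 866 without DU145-DR replicate 1 or 2, as all groups shared 1 estimate of the spread. The directions were 304 up and 236 down with all arrays, 105 and 109 without 22Rv1 replicate 2 and 105 and 114 without 22Rv1-DR replicate 1. List members that stayed past the threshold without each array in turn were 0 of 4 S phase, 2 of 4 cholesterol, 4 of 6 progenitor, 3 of 3 transporter, 5 of 8 mesenchymal, 5 of 7 luminal, 2 of 4 androgen-responsive, 1 of 2 class I and 1 of 6 interferon genes. On the third pair the list medians were -0.21 for progenitor, 0.28 for transporter, 0.08 for mesenchymal, -0.25 for luminal and -0.24 for class I genes. By fry the S phase and class I lists did not pass (adjusted p = 0.0649 and 0.116), while the interferon, glutathione S-transferase, cancer-testis, fibroblast and DU145 identity lists did (0.0454, 0.0451, 0.0314, 0.0330 and 0.0314), the last with a median of -0.13 but 0.46 on the third pair. Under the replicate block the count of changed genes was 2147, and more members passed in 34 of 37 lists and fewer in 0, among them 31 falling S phase and 12 falling cholesterol genes.

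ABCB1 headed the genes that changed the same way in both resistant lines. With it rose IGFBP3, by 3.37 ± 0.21 and 3.45 ± 0.21, NRCAM, a neuronal adhesion molecule, by 2.48 ± 0.22 and 2.91 ± 0.22, HSPB8 by 2.82 ± 0.28 and 2.28 ± 0.28, and SERPINE2, a protease inhibitor, by 1.97 ± 0.24 and 2.62 ± 0.24, in DU145-DR and 22Rv1-DR cells respectively. KRT19, CDH1 and F3 fell in both, F3, the tissue factor gene that starts coagulation, at -3.48 ± 0.28 and -3.25 ± 0.28. C1orf115 also fell, at -2.16 ± 0.27 and -2.57 ± 0.27. ARHGAP29 changed by -2.85 ± 0.38 and -2.21 ± 0.38, but its 22Rv1-DR call was lost without any 1 of the 4 arrays of 22Rv1 and 22Rv1-DR (adjusted p from 0.0568 to 0.0942). In all, 47 genes rose in both and 26 fell in both, where 16.8 and 12.9 would be shared by independent lists. Another 23 rose in DU145-DR and fell in 22Rv1-DR while 29 did the opposite, where 13.05 and 16.7 would be shared. Each gene had 1 estimate of spread for both lines, so genes of small spread tend to pass in both. Independent lists therefore understate the number expected in either direction. Over all 9713 genes the changes of the lines were barely related (r = 0.07, rho = 0.07 across genes, which are not independent replicates; r = 0.13 on the third pair). The 73 genes changed the same way became 37 and 46 without DU145 replicates 1 and 2, 120 and 145 without DU145-DR replicates 1 and 2, 25 without 22Rv1 replicate 1, 22Rv1 replicate 2 or 22Rv1-DR replicate 1, and 24 without 22Rv1-DR replicate 2. Under the replicate block they were 538, of which 310 rose and 228 fell where 227 and 156 would be shared. As a ratio to the expected number the excess was smaller, 1.37 and 1.46 against 2.80 and 2.01 without the block. Under the block 162 and 253 changed opposite ways where 171 and 207 would.

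**Figure D2:**
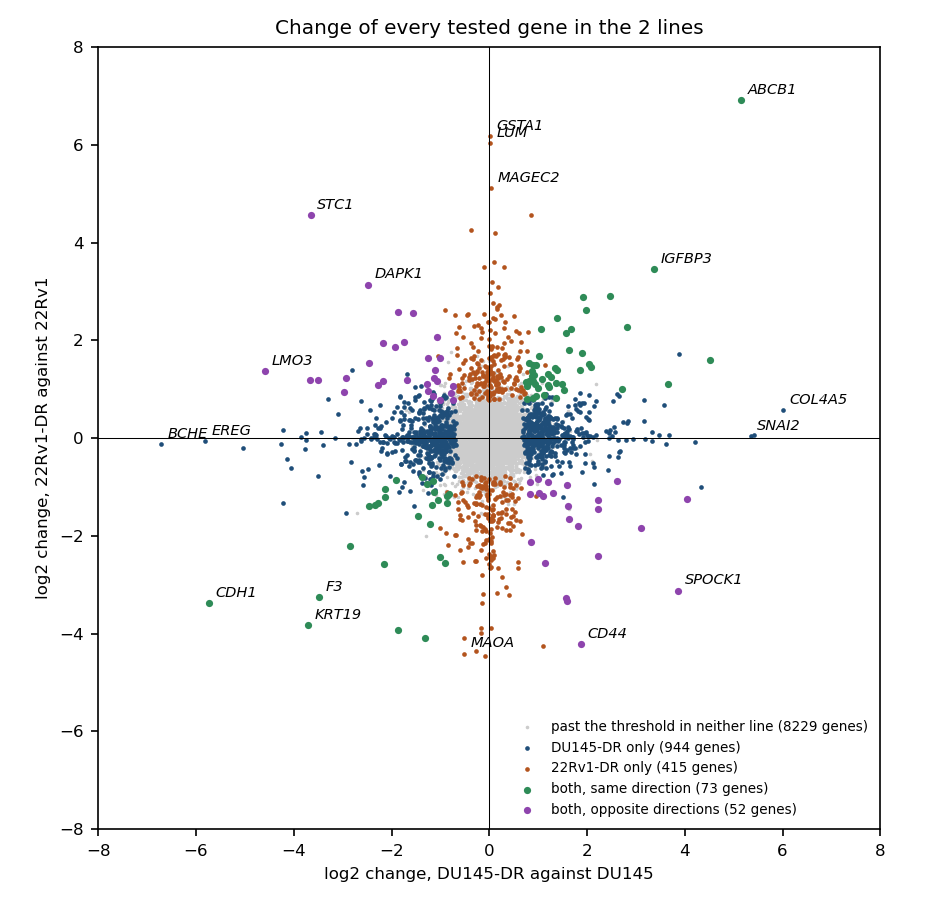
Log2 change (resistant minus parental) of each of 9713 genes in DU145-DR cells (x axis) against 22Rv1-DR cells (y axis), coloured by whether the gene passed the test in either or both lines. ABCB1 lies far up in both, 73 genes changed the same way and 52 opposite ways.

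The genes beside ABCB1 on chromosome 7 differed between the replicate pairs of DU145; their single values were chosen after they had been seen. The 10 tested genes nearest to ABCB1 had a median change of 2.27 in pair 1, -0.06 in pair 2 and 3.69 in the third pair, beside ABCB1 changes of 6.03, 4.28 and 8.64. In pairs 1 and 3, 6 of the 10 were over 1 and 2 under -1, and in pair 2 there were 0 of either. CROT, a peroxisomal acyltransferase, and ABCB4, the phospholipid transporter most similar to ABCB1, gave 2.10 ± 0.82 and 1.61 ± 0.74 over pairs 1 and 2 and 4.26 and 4.78 on the third pair. None of the 10 passed the test in DU145-DR cells, with adjusted p from 0.0949 for TMEM243 to 0.455 for SLC25A40. In 22Rv1-DR cells the neighbours' median was 0.21 over pairs 1 and 2 and 0.08 on the third pair, and only RUNDC3B rose, by 2.27 ± 0.32 (adjusted p = 0.00405; 1.55 on the third pair).

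**Figure D3:**
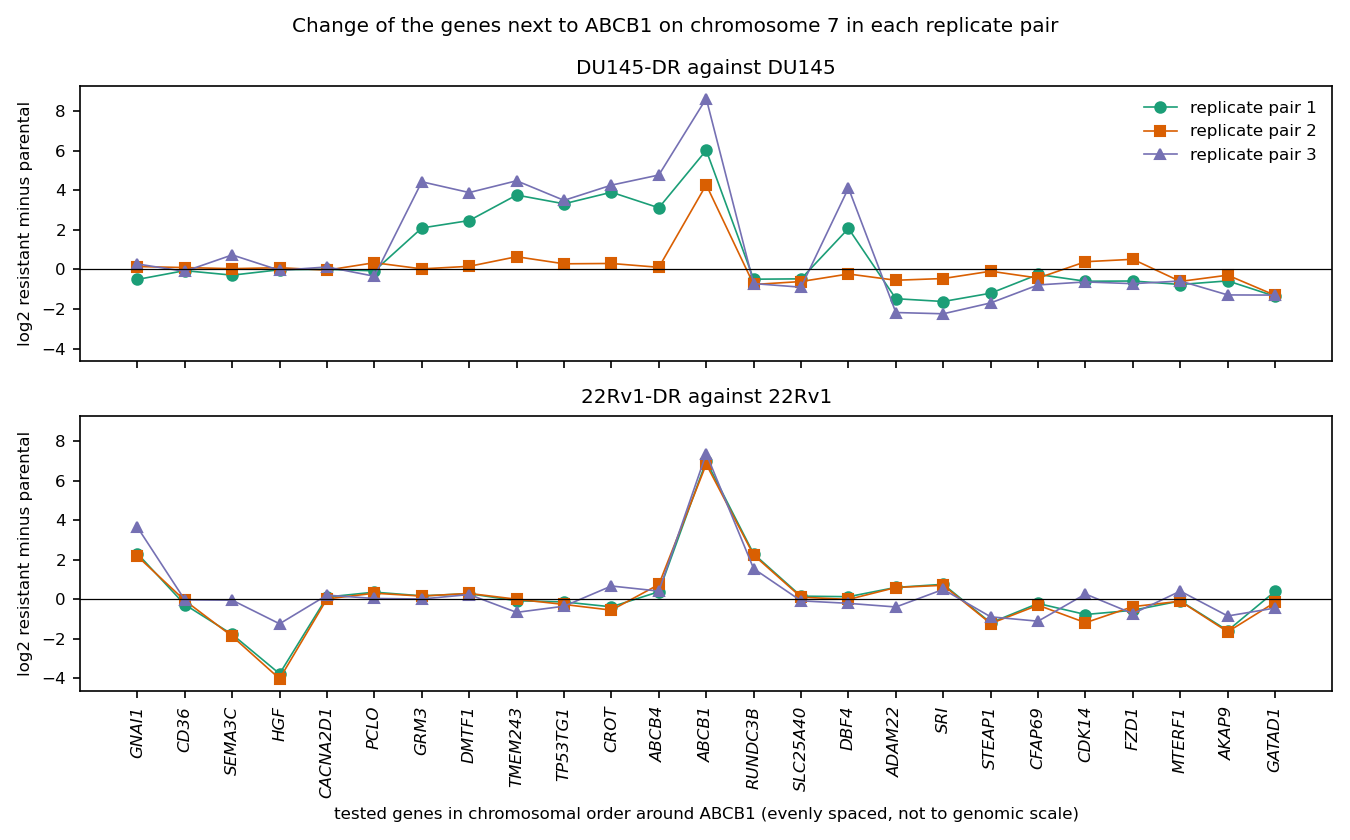
Log2 change (resistant minus parental, y axis) of ABCB1 and the 12 tested genes on each side of it, in chromosomal order (x axis), for each replicate pair of both lines. In DU145-DR cells the neighbours' median was 2.27 in pair 1 and 3.69 in pair 3 but -0.06 in pair 2.

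The changes differed between the lines for 777 genes, with 435 differences (22Rv1 change minus DU145 change) above 0 and 342 below. STC1 differed by 8.20 ± 0.27 (adjusted p = 5.98e-06): it fell by 3.65 ± 0.19 in DU145-DR and rose by 4.56 ± 0.19 in 22Rv1-DR cells. DAPK1, a death-associated kinase, fell by 2.48 ± 0.21 and rose by 3.14 ± 0.21, and CD44 rose by 1.87 ± 0.19 and fell by 4.22 ± 0.19. For ABCB1 the difference of 1.75 ± 0.71 did not pass (adjusted p = 0.197), but without DU145-DR replicate 1 it was 2.71 and passed (adjusted p = 0.000679). On the third pair, where the floors of the lines were alike, it had the opposite sign (-1.28). The parental floor was higher for DU145 on the tested arrays, so no difference in the size of the ABCB1 rise is read from them. CDH1 fell further in DU145-DR cells (difference 2.35 ± 0.32, adjusted p = 0.00361), and for KRT19 and IGFBP3 the differences of -0.13 ± 0.44 and 0.08 ± 0.29 did not pass (adjusted p = 0.970 and 0.974).

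Among gene lists, interferon-induced genes differed by a median of 0.95 (13 of 34 higher, 0 lower, 21 not past; adjusted p = 9.73e-08; adjusted p = 0.383 with an estimated correlation). In 22Rv1-DR cells alone 5 of them rose and 1 fell (list adjusted p = 0.0749), with SP100, a nuclear body protein, up by 1.83 ± 0.21. Only the SP100 call stayed without each array in turn. Those of IFITM1, IFITM2 and IFITM3 were lost without 22Rv1 replicate 1 (adjusted p = 0.0687, 0.117 and 0.107), 22Rv1 replicate 2 (0.0568, 0.233 and 0.239) or 22Rv1-DR replicate 1 (0.0800, 0.216 and 0.173), those of IFITM2 and IFITM3 also without 22Rv1-DR replicate 2 (0.134 and 0.183) and that of IFITM3 without DU145 replicate 1 or 2 (0.0528). The BST2 call was lost without 22Rv1 replicate 2 (0.127) or 22Rv1-DR replicates 1 and 2 (0.0574 and 0.112). S phase genes differed by -0.53 (0 higher, 7 lower, 33 not past; adjusted p = 4.02e-07; adjusted p = 0.682 with an estimated correlation). Their median in DU145-DR cells was 0.05 (1 of 40, POLA1, rose, a call lost without DU145 replicate 2 with adjusted p = 0.0635, and 39 did not pass; adjusted p = 0.709), but 1.09 on the third pair. Immediate early genes differed by -0.58 (1 higher, 6 lower, 16 not past; adjusted p = 0.000720; adjusted p = 0.383 with an estimated correlation), and DUSP4 rose by 2.22 ± 0.20 in DU145-DR and fell by 2.41 ± 0.20 in 22Rv1-DR cells. Class I genes differed by 0.57 (6 higher, 0 lower, 12 not past) and hypoxia genes by -0.28 (0 higher, 4 lower, 24 not past), both with adjusted p = 0.0467 and adjusted p = 0.736 with an estimated correlation. The class I call was lost without DU145 replicate 1 or 2 (adjusted p = 0.0564 and 0.0560), and the hypoxia call without DU145 replicate 1 or DU145-DR replicate 1 (0.105 and 0.155); both were lost with the replicate number as a block (0.0574) and after quantile normalization (0.0806 and 0.0875). Adjusted over each list alone, 18 interferon genes were higher and 2 lower, 12 S phase genes lower, 1 immediate early gene higher and 8 lower, 6 class I genes higher and 1 lower, and 4 hypoxia genes lower.

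The count of 777 was 314 and 339 without 22Rv1 replicates 1 and 2, 336 and 331 without 22Rv1-DR replicates 1 and 2, 465 without DU145 replicate 2 and 1280 without DU145-DR replicate 2. Without DU145-DR replicate 1 it was 1067, with 505 above 0 and 562 below, and without DU145 replicate 2 there were 223 above and 242 below. Members that stayed past without each array were 5 of 13 interferon, 0 of 7 S phase, 3 of 7 immediate early, 1 of 6 class I and 3 of 4 hypoxia genes. By fry the S phase, class I and hypoxia differences did not pass (adjusted p = 0.109, 0.0904 and 0.0914), while those of the transporter, luminal, class II, progenitor, inflammatory and DU145 identity lists did (0.0109, 0.0226, 0.0445, 0.00585, 0.0148 and 0.0445); the progenitor and DU145 identity medians were -0.23 and -0.41 but 0.08 and 1.23 on the third pair. The median difference on the third pair was 0.55 for class I, -0.22 for hypoxia, -0.55 for immediate early and -1.26 for S phase genes. The count was 3080 with the replicate number as a block and 1229 after quantile normalization of the arrays.

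**Figure D4:**
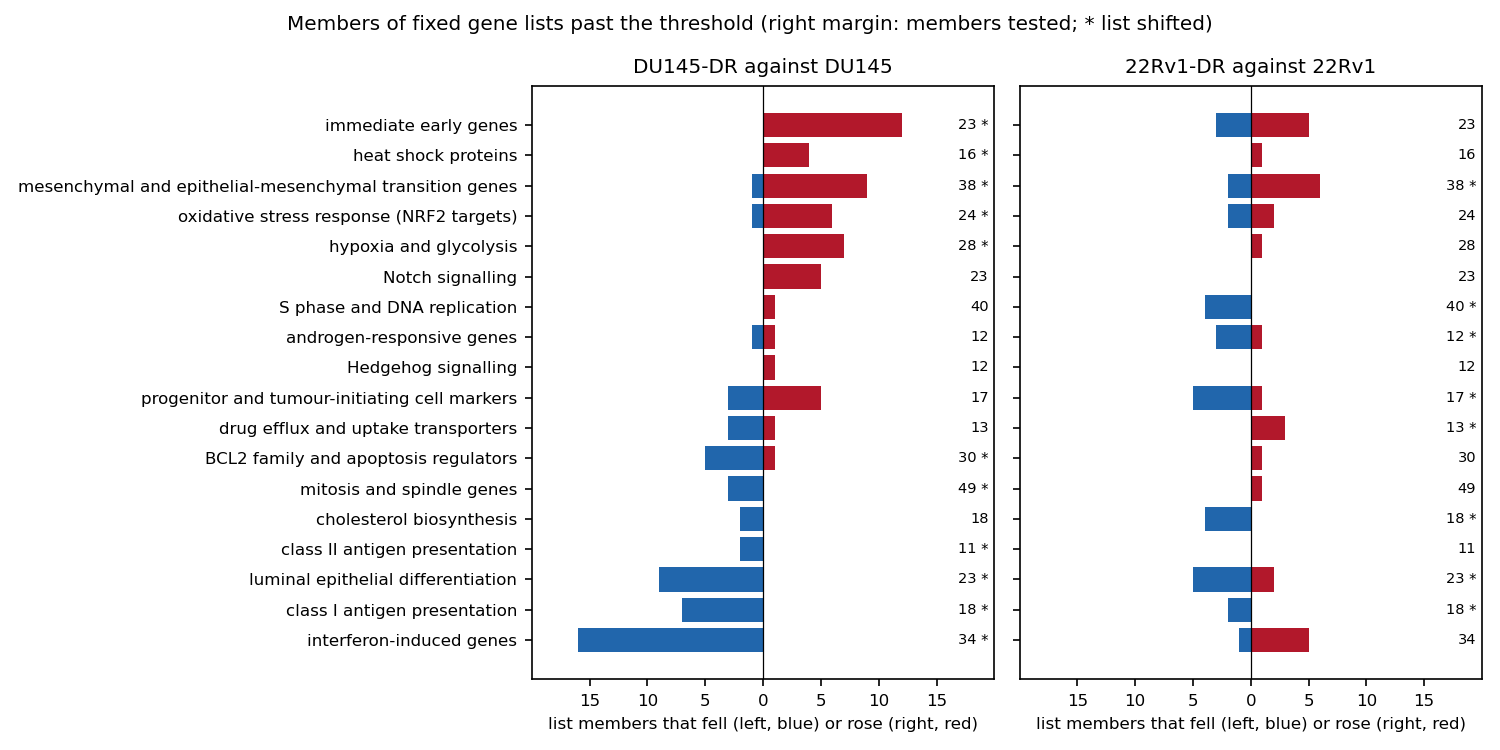
Number of tested genes that rose (right of 0) or fell (left of 0) in each resistant line for the shifted gene lists and for Notch and Hedgehog signalling, with the members tested at the right and an asterisk for a list shifted by camera. Interferon-induced genes had 16 falls in DU145-DR and 1 in 22Rv1-DR cells; S phase genes had 0 and 4.

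The parental lines differed in the identity markers of each line. After quantile normalization, KLK2, a kallikrein of prostate epithelium, was higher in 22Rv1 than in DU145 cells by 3.97 ± 0.26, the prostate transcription factor gene HOXB13 by 3.82 ± 0.24 and KLK3 by 3.06 ± 0.31, and VIM, CAV1 and ANXA1 were lower, at -5.49 ± 0.20, -5.55 ± 0.33 and -5.43 ± 0.15. In the resistant lines KLK2 still differed by 4.33 and VIM by -7.21, but KRT7 went from -4.64 to -0.37 (from -7.21 to -1.04 on the third pair) and EGFR from -1.56 to -0.22 (from -1.63 to -1.79). TRPM8 was the exception among the 22Rv1 markers, at -0.72 ± 0.21 on these arrays and 0.10 on the third pair. As deposited, 8097 of 9713 genes differed, 363 higher in 22Rv1 and 7734 lower, with a median difference of -1.31 over all genes. After quantile normalization, where the median was 0.05, 4404 differed, 2332 higher and 2072 lower, so intensities are not compared between lines.

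The third pair mostly had the sign of the tested arrays. Of the 1069 genes changed in DU145-DR cells, 1009 had the same sign there (94.4%, 95% exact binomial interval 92.8 to 95.7). Of the 540 changed in 22Rv1-DR cells, 485 did (89.8%, 86.9 to 92.2). Among all genes tested the shares were 72.5% and 61.5%. Across all genes, which are not independent replicates, r was 0.73 for DU145 and 0.60 for 22Rv1. Named genes that changed in DU145-DR cells with the opposite sign on the third pair were HES1, CXCR4, CXCL8, AKR1B10, EGR1, EGFR and MAGEB2, at -0.37, -1.11, -0.89, -2.10, -1.75, 0.53 and -0.04 there. In 22Rv1-DR cells they were GADD45A, PLPP1, E2F1, ACAT2, HMGCS1, P4HA2 and AMBP, at -0.21, 0.09, 0.02, 0.01, 0.37, -0.34 and 0.08.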

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

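Of the tests given in this part, the per-pair tests of the neighbours of ABCB1 and, for S phase genes, those of a smaller dividing share and of a state of the first array pairs were chosen after the results they measure had been seen.

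ABCB1 rose in both resistant lines, and its neighbours on chromosome 7 were examined as a possible source. The neighbours' median change lay at percentile 99.9 of all such medians in DU145 and 90.5 in 22Rv1, and by replicate pair of DU145 it lay at 99.9, 30.3 and 99.9. A gain or shared activation of most of the region would go with DU145 pairs 1 and 3. The medians of DU145 pair 2, where ABCB1 still differed by 4.28, and of 22Rv1 argue against it for those arrays only. A median of 10 neighbours cannot see a shorter stretch, and in 22Rv1-DR the adjacent gene RUNDC3B rose by 2.27 ± 0.32. Cross-hybridization of the paralog ABCB4 was taken to give equal changes, and ABCB1 exceeded ABCB4 by 3.54 in DU145 and 6.34 in 22Rv1. These values argue against it only under that assumption, as parental ABCB1 values lay near the floor. In DU145 pairs 1, 2 and 3 ABCB4 changed by 3.12, 0.11 and 4.78, beside 6.03, 4.28 and 8.64 for ABCB1. The resistant cells may thus have raised ABCB1 with and without most of its neighbours. No DNA measurement was used to test this hypothesis here.

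Interferon-induced genes differed between the lines by a median of 0.95, by camera on limma's test of the difference (adjusted p = 9.73e-08; adjusted p = 0.383 with an estimated correlation). Unequal scaling of the lines on the 8 arrays was argued against by the third pair, from another table, where the median difference was 1.49. A single replicate pair as the source was argued against by the smallest difference over the 3 pairs, 0.902. A biological difference between the resistant lines may remain, as a hypothesis found and tested on the same data, with resistance and drug exposure confounded.

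S phase genes differed between the lines by a median of -0.53 (adjusted p = 4.02e-07; adjusted p = 0.682 with an estimated correlation, 0.109 by fry), and their median in 22Rv1-DR was -0.65. Fewer dividing cells alone would lower mitosis genes alike, but the larger of the S phase minus mitosis medians in pairs 1 and 2 was -0.492. In pair 3 that contrast was only -0.04, so it was not seen where S phase genes barely fell. The brightness of the probe sets was argued against by 10000 random lists matched for it, of which 0% had a median as low, the lowest being -0.19. The third pair had a median of only -0.08, at percentile 4.25 of matched lists, so the fall in 22Rv1-DR may be a state of the first 2 array pairs. The difference between the lines was larger on the third pair, -1.26 at percentile 0, where the median in DU145-DR was 1.09, so its source is left open.

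The other results singled out by limma's or camera's test of the difference between lines (22Rv1 change minus DU145 change) are given as values. The number of genes that differed was 777. STC1 differed by 8.20, SPOCK1 by -6.99, BCHE by 6.60, GSTA1 by 6.16, CD44 by -6.09, LUM by 6.02, LMO3 by 5.96, EREG by 5.75, DAPK1 by 5.62 and COL4A5 by -5.43. The median difference was 0.57 for class I genes, -0.28 for hypoxia genes and -0.58 for immediate early genes.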

How the results depend on the processing

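Chosen after the data were seen were the filter percentile within each array, quantile normalization within each line, the estimated correlation with the block and the same sign in each pair; all other alternatives were planned. For named genes, 10916 values kept their side of the threshold, 337 came to pass, 777 no longer passed and 0 reversed. For lists the numbers were 2349, 96, 128 and 1. A change of sign counted as a reversal only for a gene that passed as reported or under the alternative, and for a list that passed as reported. Other changes of sign were not counted. The mitosis list in DU145-DR reversed without DU145-DR replicate 1, with adjusted p from 7.28e-10 to 0.475 over the arrays left out. ABCB1, CDH1, KRT19, IGFBP3, SNAI2, STC1, CD44, F3, SERPINE2, NRCAM and HEY1 kept their calls in the lines where they were called under every alternative run; of 116, 92 and 109 named calls in DU145-DR, 22Rv1-DR and the difference, 60, 45 and 63 did. Low signal over background limits the dim genes. The cause was not tested for the values that follow, except that fewer arrays leave fewer degrees of freedom and a stricter threshold passes fewer genes.

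Counts are in the order DU145-DR, 22Rv1-DR, difference, same way in both, where each moved by over 1.5 times. With the replicate number as a block they were 3445, 2147, 3080 and 538; with 12 arrays and the replicate as a block 2951, 858, 1978 and 184; at an adjusted p under 0.01 they were 399, 260, 296 and 22. With 12 arrays and the table as a block, DU145-DR had 2089, the difference 1335 and same way 114. With only the 4 arrays compared, DU145-DR had 292 and 22Rv1-DR 1266. After quantile normalization the difference had 1229, same way 136 and the parental lines 4404; after a shift to 1 median the parental lines had 4056; same way had 133 with quantile normalization within each line and 47 at a log2 change of at least 1.

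Of the lists shifted (11, 8 and 5 in DU145-DR, 22Rv1-DR and the difference), 0, 0 and 0 remained with an estimated correlation, with or without the block. In 22Rv1-DR there were 5 with the mean of probe sets, with the replicate block and with quantile normalization within each line. For the difference there were 3 with quantile normalization, over all arrays or within each line, a shift to 1 median, the replicate block or a filter percentile within each array; 8 with no filter, with either 12-array fit or by fry; 11 with a pseudocount of 1; and 14 with the mean of probe sets. Agreement in sign with the third pair was 92.7% and 86.6% after quantile normalization and 92.6% and 86.2% with it within each line.

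Without 1 array, the ranges were 489 to 1523 genes in DU145-DR, 214 to 866 in 22Rv1-DR, 314 to 1280 for the difference, 24 to 145 the same way and 7134 to 8416 for the parental lines; 9 to 12, 7 to 11 and 4 to 10 lists; r from 0.0564 to 0.0790; and agreement from 90.3% to 96.3% and from 86.7% to 94.2%. The difference could not be fitted from only the 4 arrays compared, and lists were not run there or with every probe set tested.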

Other observations

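Of the tests in this part none was chosen after its result was seen, but the runs of genes named here were picked from a scan after their values were seen, as was the wording of the hypothesis.

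Gene groups not yet described gave these counts. Inflammatory and NF-kappaB genes: 7 of 28 fell and 2 rose in DU145-DR cells (list adjusted p = 0.217), and 1 rose in 22Rv1-DR cells (0.799). LCN2, an iron-binding protein of inflammation, fell by 2.88 ± 0.18 and ICAM1, an adhesion molecule, fell by 2.65 ± 0.24 in DU145-DR cells. Glutathione S-transferase, cytochrome P450 and glucuronidation genes had 3 of 18 falling in DU145-DR cells (0.279) and 3 rising and 1 falling in 22Rv1-DR cells (0.169); CYP1A1 rose by 1.84 ± 0.24 and GSTM3 fell by 3.20 ± 0.43 there. Growth factor receptors had 1 of 22 rising and 2 falling in DU145-DR cells (0.279), and 1 and 3 in 22Rv1-DR cells (0.327); ERBB3 fell by 2.47 ± 0.23 in DU145-DR cells. Genes of tubulins and microtubule-binding proteins had 3 of 32 rising in DU145-DR cells (0.504, with a median of -0.05 and a mean of 0.13). In 22Rv1-DR cells 1 rose and 1 fell (0.813). TUBA1A rose by 2.19 ± 0.24 in DU145-DR cells, and TUBB3, a beta-tubulin, gave 0.41 ± 0.20 and -0.18 ± 0.20 (adjusted p = 0.255 and 0.873). Proteasome subunits had 5 of 26 rising in DU145-DR cells (0.0650) and 1 in 22Rv1-DR cells (0.799; median -0.02, mean 0.00). Without DU145 replicate 1 all 5 proteasome calls of DU145-DR cells were lost (PSMC3, PSMC4, PSMD1, PSMD14 and PSMD2; adjusted p = 0.0590, 0.0853, 0.184, 0.144 and 0.192), as were the 3 of the glutathione S-transferase group (GSTA4, GSTK1 and GSTT1; 0.0734, 0.140 and 0.0634). In DU145-DR cells progenitor markers had 5 of 17 rising and 3 falling (adjusted p = 0.706), cholesterol genes 2 of 18 falling (0.0716), and androgen-responsive genes 1 of 12 rising and 1 falling (0.957; median 0.02, test downwards), with KLK3 at 0.06 ± 0.39. In 22Rv1-DR cells class II genes had 0 of 11 rising or falling (0.799), BCL2 family genes 1 of 30 rising (0.631), NRF2 targets 2 of 24 rising and 2 falling (0.642), hypoxia genes 1 of 28 rising (0.642), heat shock genes 1 of 16 rising (0.496), and immediate early genes 5 of 23 rising and 3 falling (0.437).

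For the remaining lists the counts in DU145-DR and then in 22Rv1-DR cells were as follows, with the adjusted p of the list. Basal epithelial markers: 1 of 11 rose and 1 fell (0.279), then 0 (0.830). Neuroendocrine markers: 1 of 12 rose (0.504), then 1 (0.507; median -0.05, mean 0.25). Targets of p53: 1 of 20 rose and 2 fell (0.504), then 2 rose (0.327). Unfolded protein response: 2 of 24 rose (0.736; median -0.05, mean 0.03), then 1 (0.642). Cancer-testis antigens: 1 of 10 rose (0.678), then 1 (0.617; median -0.06, mean 0.47). Chromatin modifiers: 1 of 18 rose (0.339), then 1 (0.272). Ribosomal proteins: 0 of 43 (0.335), then 0 (0.363). Oxidative phosphorylation: 2 of 45 fell (0.156), then 0 (0.345). Leukocyte markers: 0 of 11 (0.871), then 0 (0.813). Endothelial markers: 0 of 6 (0.764), then 0 (0.981; median 0.02, test downwards). Fibroblast markers: 2 of 11 rose, FBN1 by 2.02 ± 0.30 and FBLN1 at 0.89 ± 0.22, a call lost without any 1 of 7 arrays, all except DU145-DR replicate 1, at 0.0724 to 0.179 (0.268), then 2, LUM by 6.04 ± 0.23 and COL6A3 by 3.09 ± 0.23 (0.0801). Hepatocyte markers: 2 of 11 fell (0.376), then 3 rose and 2 fell (0.755; median -0.01, mean 0.21). DU145 identity markers: 2 of 9 rose and 3 fell (0.871; mean -0.25, test upwards), then 3 fell (0.169). In both paragraphs on lists, calls of which 0 stayed without each array in turn were those of the androgen-responsive, glutathione S-transferase, proteasome, chromatin and oxidative phosphorylation genes in DU145-DR, and of the inflammatory, p53, neuroendocrine, growth factor receptor, hypoxia, proteasome and chromatin genes in 22Rv1-DR cells. With the replicate number as a block more members passed in most lists, 33 and 34 of 37. The 22Rv1 identity list had under 5 tested genes; the medians on the third pair were -0.14 and -0.37.

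On the larger array type alone, 1 array per group with no test, DU145-DR was higher than DU145 for DMTF1-AS1 by 6.19, ELAPOR2 by 5.04, MIR100HG by 3.78, EID3 by 3.26 and IRX3 by 3.20. DMTF1-AS1 and ELAPOR2 lie on chromosome 7 beside DMTF1, a tested neighbour of ABCB1. They thus belong to the stretch near ABCB1 in which most tested neighbours were higher on the third pair. SFTA3 differed by -6.42, MAL2 by -5.59, FAM83A by -5.44, SUSD2 by -5.20 and CFAP251 by -4.86. In 22Rv1-DR, PLPP4 was higher by 5.47, SLC6A19 by 4.11, DCDC2 by 3.41, SSTR5-AS1 by 3.07 and LINC00324 by 2.99, and DOCK8 differed by -5.56, TUNAR by -4.55, PRR15 by -4.17, DOCK8-AS1 by -3.63 and CREB3L4 by -3.54. GLI1 was dim there too, at 37.3 and 40.8 in DU145 and DU145-DR and 48.2 and 29.9 in 22Rv1 and 22Rv1-DR.

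One hypothesis is that stretches of chromosomes were gained or lost in the resistant lines. Of 9247 windows of 21 neighbouring genes, 399 had an absolute median change of at least 0.4 in DU145 (154 up, 245 down; highest of 1000 shuffles 32) and 39 in 22Rv1 (all up; highest 14), so a chance order of genes was argued against in both. In DU145, 98.7% of these windows had the same sign on the third pair. The longest runs were on chromosome 8 from OSGIN2 to DERL1, 67 genes with a median of 0.41 (0.64 on the third pair), and on chromosome 7 from RUNDC3B to ZCWPW1, 57 genes with a median of -0.43 (-0.72). A copy number change is a candidate explanation in DU145, although co-regulated neighbours could give the same windows and no DNA data were used here. In 22Rv1 82.1% had the same sign, but the runs had third-pair medians of only -0.02 to 0.21.

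With all 12 arrays in 1 fit and the table as a block, the real split of the 6 arrays of DU145 gave 2089 genes and the highest other split 6; for 22Rv1 the values were 625 and 0. In each line 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.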
